A study of Homo sapiens with 4 samples.

How the data were processed

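RNA was profiled in 4 libraries of J.gamma1 cells, a Jurkat-derived human T-cell acute lymphoblastic leukemia (T-ALL) line that lacks phospholipase C gamma 1. Per the labels, 2 libraries came from cells with a control short hairpin RNA (shNC) and 2 from cells with a hairpin against ELOVL5 (shELOVL5). Per the labels' protocols, total RNA was isolated with TRIzol and made into libraries with an Illumina TruSeq RNA kit. The sequence of the hairpin is not given in the sources used here.

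The deposited table holds whole-number read counts per gene, not normalized, for 64252 Ensembl gene identifiers. Per the submitters' processing notes, which list tools without their order or role, HISAT2 2.2.0, StringTie (version not given) and genome build hg38 were used. The annotation release, the step that turned alignments into counts and its use of strand are not given in the sources used here. Values for overlapping genes, antisense pairs and near-identical copies are therefore uncertain. Symbols were taken from a gene name table that matched 56105 identifiers, and 41481 identifiers had a symbol. Coordinates and transcript sequences came from GENCODE release 29 on GRCh38, which held 56591 of the identifiers on its primary assembly. The other 7661, such as copies on alternate haplotypes, held 2.10% of all counts and stayed in the tests. Counts were 0 in every library for 32824 identifiers.

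Each library was assigned to its group and replicate number by its title. Total counts per library lay between 16254002 and 17338719, so that 3 counts corresponded to 0.172 to 0.187 CPM (counts scaled to library size). A count of 0 was taken to allow up to 3 counts per library, a limit that covers counting error only.

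The comparison of shELOVL5 with shNC was fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit with robust=TRUE, glmQLFTest) was two-sided with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all tested genes from that test unless another test is named, with a threshold of 0.05. Log2 fold changes are shELOVL5 over shNC. Levels are TMM-scaled CPM, given as mean ± SD with n = 2 per group.

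The tests, the settings, their 14 alternatives, the named-gene rule and 28 gene lists were chosen before the data were examined. The rule named ELOVL5 and PLCG1, then the 12 largest rises and 12 largest falls. Those had to pass the threshold, reach a mean of 5 CPM, show no overlap between the groups' libraries and carry an ordinary symbol, which left out symbols ending in P and digits. It also named up to 4 members per list with the smallest p, or, for lists of other cell types, with the highest CPM. Members named as the few exceptions to the direction of a list were chosen after their values were seen.

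The lists covered fatty acid elongation and desaturation, fatty acid and glycerolipid synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPAR targets, ferroptosis and antioxidant response, and the integrated stress and unfolded protein response. They also covered G1/S and DNA replication, G2/M and mitosis, p53 targets and cell cycle inhibitors, apoptosis regulators, the NOTCH1 and T-ALL oncogene programme, MYC targets and ribosome biogenesis, T cell receptor and surface genes, immediate early genes, NF-kB targets, the PI3K pathway and JAK-STAT genes. The remaining lists held interferon response genes, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, migration and adhesion, ribosomal proteins, mitochondrially encoded genes, histones, and markers of B, myeloid, erythroid and epithelial or fibroblast cells. Lists were tested against other genes with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation and fry were the alternatives, and the elongation list without ELOVL5 was added after seeing the data. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the design, so few lists can pass.

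The other alternatives were RLE size factors, scaling by total counts only, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust=FALSE, a replicate block, symbol-bearing genes only, a test against a fold of 1.2 (glmTreat), and leaving out each library. A further 4 lists, on aminoacyl-tRNA synthetases, amino acid transporters, translation factors and targets of SRF and MRTF, were chosen after the results were seen and adjusted among themselves. So was a scan of 3′ untranslated regions (UTRs) for 4096 hexamers in 9965 genes with a mean of at least 8 CPM. It compared residual fold changes of genes with and without each hexamer, against 100 shuffles.

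The fit was tested on simulated counts for shELOVL5 against shNC with known changes, of which 17053 genes were tested. It recovered 16% of genes changed 1.25-fold, 56.2% at 1.5-fold, 72.9% at 2-fold and 83.7% at 4-fold, with 5 false calls among 16858 unchanged genes. Each of these folds was given to only 48 to 50 tested genes. In the data 20.4% of genes passed, so recovery and false calls there may differ. Simulated genes also took their spread from the trend fitted over expression, so genes of unusual spread were not represented. The set test on simulated counts called the planted set, and the hexamer scan ranked 2 of 2 planted hexamers first. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the scan, the permutation tests and the plots. No sample was left out. Some genes that the rule names are not reported here.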

Results

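Gene expression was measured by RNA sequencing in J.gamma1 cells with a control hairpin or a hairpin against ELOVL5, with 2 libraries per group. Total counts were 17246603 and 16254002 in the shNC libraries and 17338719 and 16311139 in the shELOVL5 libraries. The 10 most abundant genes took 4.26% to 4.58% of the counts in each library. Libraries of 1 group were closer to each other than to the other group. Chi-square per degree of freedom was 6.58 between the shNC libraries and 6.15 between the shELOVL5 libraries, against 31.4 to 34.4 between groups, and the replicates were therefore treated as separate libraries. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

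The comparison asked what changes in the transcriptome of these leukemia cells when ELOVL5, an elongase of polyunsaturated fatty acids, is knocked down. ELOVL5 (ENSG00000012660, GRCh38 chromosome 6, 53267398 to 53349179) was lower in both shELOVL5 libraries, with 1255 and 1157 counts against 5816 and 5664. Its level was 348 ± 7.47 CPM in shNC and 70.9 ± 1.27 CPM in shELOVL5 (SD, n = 2), 4.90-fold lower (log2 fold change -2.29, SE 0.0486, adjusted p = 1.79e-09). PLCG1 (ENSG00000124181, chromosome 20, 41136960 to 41196801), the gene of the protein that the line lacks, still gave transcripts at 324 ± 11.4 and 299 ± 2.37 CPM. Its log2 fold change of -0.12 did not pass (adjusted p = 0.0832), though it did without shNC replicate 1 (adjusted p = 0.0364).

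**Figure D1:**
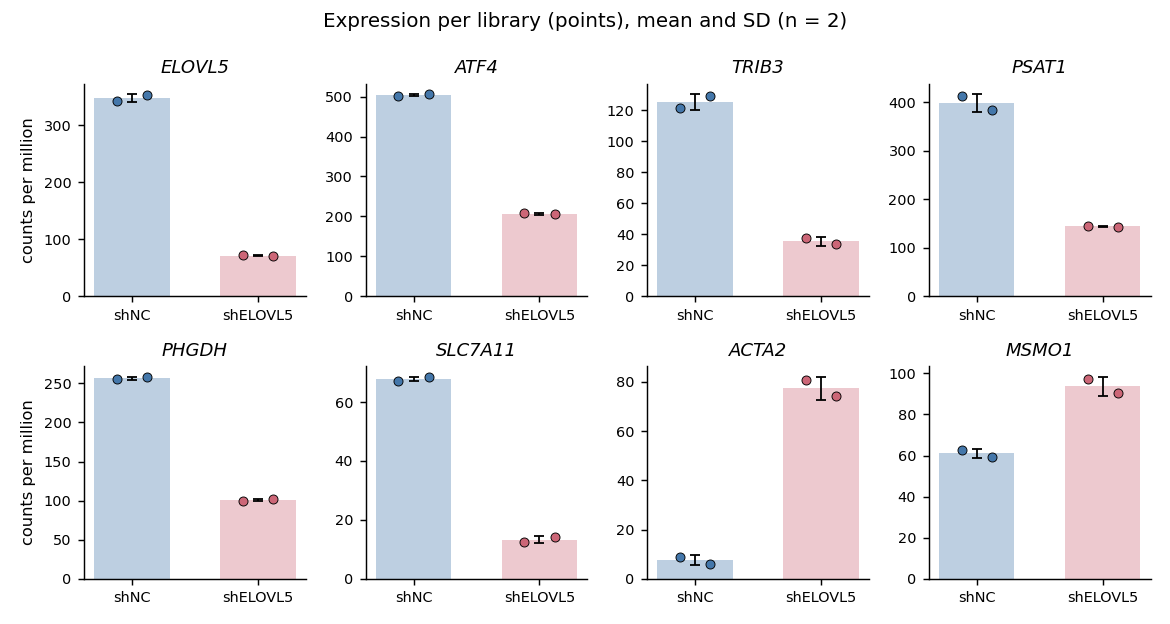
TMM-scaled CPM (vertical axes, from 0) of 8 genes in shNC and shELOVL5 cells, with points for single libraries, bars for means and error bars for SD (n = 2). ELOVL5 fell from 348 to 70.9 CPM and ATF4 from 505 to 207 CPM, while ACTA2 rose from 7.56 to 77.4 CPM.

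Expression changed widely, with 1610 genes higher and 1952 lower in shELOVL5 among 17461 tested (20.4%). At least a 2-fold change was seen for 188 of the higher and 230 of the lower genes. Among genes that met the naming rule, ASS1, which encodes the argininosuccinate synthase of arginine synthesis, fell most, from 48.7 ± 2.07 to 5.77 ± 1.06 CPM (log2 fold change -3.07, SE 0.145, adjusted p = 4.96e-07). CCR2, a chemokine receptor gene, fell by 2.39 on the log2 scale, SLC7A11, which encodes the cystine transporter, by 2.35, and ALDH1A2, which encodes an enzyme of retinoic acid synthesis, from 303 ± 4.40 to 74.2 ± 2.88 CPM. EGFL7, SNX32, TRIB3, CYB5R4, KCNQ3, NDUFA4L2 and MARCKS followed, with log2 fold changes of -1.95 to -1.71. ACTA2, the gene of smooth muscle alpha actin, rose from 7.56 ± 1.97 to 77.4 ± 4.71 CPM (log2 fold change 3.35, SE 0.154, adjusted p = 1.78e-06), and ACTG2, that of smooth muscle gamma actin, from 13.4 ± 1.74 to 51.3 ± 3.40 CPM. The abundant actin genes ACTB and ACTG1, chosen after their values were seen, rose by 0.27 and 0.17 on the log2 scale. PRR5L, RGS3, LGALS1, ADRB1, CTHRC1, ADORA2A and GLIPR1 rose with log2 fold changes of 1.46 to 1.88. The purinergic receptor gene P2RX1 (2.21) and the chemokine receptor gene CXCR3 (1.89) passed with all 4 libraries but not without shELOVL5 replicate 1 (adjusted p = 0.104 and 0.0966) or replicate 2 (adjusted p = 0.101 for both). The readthrough gene ISY1-RAB43 had 0 counts in both shNC libraries and 288 and 241 in shELOVL5, at least 85.45-fold higher than 3 counts per library allow. The overlapping gene RAB43 fell from 1161 and 1272 counts to 753 and 808, and the sum of both genes was 1161 and 1272 in shNC against 1041 and 1049 in shELOVL5.

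The libraries of the groups did not overlap for all 3562 genes that passed, and for 60.2% of tested genes, where chance gives 33.3%. Without shELOVL5 replicate 1 the counts were 696 higher and 1176 lower, without replicate 2 they were 795 and 1178, and 408 and 641 genes passed a test against a 1.2-fold change.

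**Figure D2:**
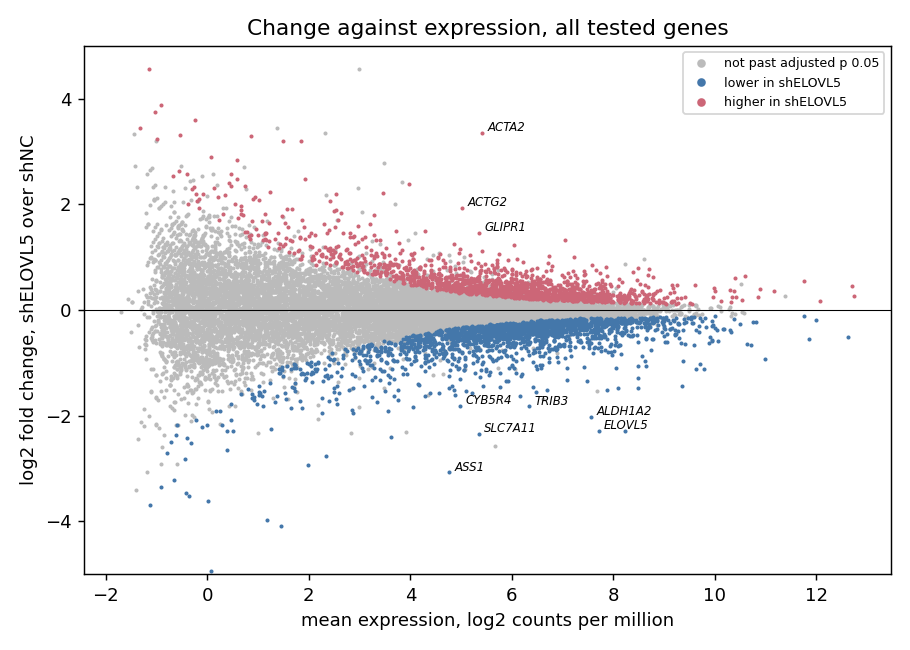
Log2 fold change of shELOVL5 over shNC against mean expression (log2 CPM), 1 point per tested gene, in red for the 1610 higher and in blue for the 1952 lower genes. Labels mark genes among the largest changes with a mean of at least 20 CPM, and 13 genes lie outside the plotted range.

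Most genes on the integrated stress and unfolded protein response list fell, but its unfolded protein response genes were mixed. Of these, CALR, HERPUD1 and EDEM1 fell and HSP90B1 and DNAJC3 rose. HSPA5, DNAJB9, SDF2L1, SEL1L, CRELD2, PDIA4 and XBP1 did not pass. Of 29 on that list, 18 fell and 3 rose, and 18 fell and 4 rose adjusted over the list alone. ATF4, the transcription factor at the centre of the amino acid stress response, fell from 505 ± 2.70 to 207 ± 2.41 CPM (log2 fold change -1.29, SE 0.0396, adjusted p = 1.95e-08). PSAT1 and PHGDH, which encode enzymes of serine synthesis, fell by 1.47 and 1.35 on the log2 scale, and SLC7A5, which encodes a large neutral amino acid transporter, fell from 1086 ± 11.1 to 498 ± 18.4 CPM. The 3 that rose were the endoplasmic reticulum chaperone genes HSP90B1 (0.22) and DNAJC3 (0.22) and the mTORC1 inhibitor gene DDIT4 (0.25). The list was lower than other genes by camera (median log2 fold change -0.65, adjusted p = 1.3e-39), but not with an estimated correlation (adjusted p = 0.12 with an estimated correlation). Of 24 ferroptosis and antioxidant genes 8 fell, with 10 lower adjusted over the list alone, and TFRC, the transferrin receptor gene, rose (0.18). SLC7A11 and its partner subunit gene SLC3A2 (359 ± 7.25 to 169 ± 7.10 CPM) fell, as did the ferritin genes FTL (-0.82) and FTH1 (-0.59). This list was also lower by camera (adjusted p = 1.97e-09, adjusted p = 0.41 with an estimated correlation), and it shares SLC7A11 and CHAC1 with the stress list. TFRC did not pass without shELOVL5 replicate 1, where 1 of the 3 stress genes rose.

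Lipid genes moved in both directions. In fatty acid elongation and desaturation, 7 of 23 genes fell and 4 rose, the same numbers adjusted over the list alone. Besides ELOVL5, the dehydratase gene HACD3 fell from 132 ± 6.87 to 45.4 ± 6.79 CPM (log2 fold change -1.55), and the desaturase genes FADS1 (-0.35) and SCD (-0.30) fell less. Camera placed this list lower with ELOVL5 included (adjusted p = 0.00471, adjusted p = 0.41 with an estimated correlation, median -0.043). Without ELOVL5, an alternative chosen after seeing the data, the other 22 genes did not pass by camera (adjusted p = 0.455, median -0.034, mean 0.016) and passed as lower by fry (adjusted p = 0.0372). In cholesterol synthesis and uptake, 8 of 24 genes rose and FDFT1 fell (-0.14, though not by total counts alone, nor without shNC replicate 1 or either shELOVL5 library), the same numbers adjusted over the list alone, and the set test did not pass (adjusted p = 0.0583). MSMO1, which encodes a sterol monooxygenase of cholesterol synthesis, rose from 61.0 ± 2.38 to 93.7 ± 4.73 CPM, and STARD4 rose by 0.37 on the log2 scale. In fatty acid and glycerolipid synthesis, 6 of 22 genes fell and 2 rose, 7 and 2 adjusted over the list alone. SREBF1, which encodes a sterol-responsive transcription factor of fatty acid synthesis, fell by 0.54 on the log2 scale and ACLY by 0.22, while DGAT2 (0.67) and AGPAT3 (0.47) rose. That set did not pass (adjusted p = 0.495), with a median of 0.012, a mean of -0.044 and a downward test. Of 24 genes of fatty acid oxidation and PPAR targets 4 fell and 2 rose, the same numbers adjusted over the list alone. HADHA, a trifunctional protein gene, fell from 153 ± 6.39 to 53.4 ± 0.785 CPM and HADH by 0.42 on the log2 scale, and ETFB (0.30) and DECR1 (0.38) rose. The set did not pass (adjusted p = 0.395), and its test was downward with a median of 0.003 and a mean of 0.001. Without shELOVL5 replicate 1, 4 elongation genes fell and 1 rose, 5 cholesterol genes rose, 2 synthesis and 2 oxidation genes fell, and ETFB (adjusted p = 0.0732) and DECR1 (0.138) did not pass. Without shELOVL5 replicate 2, 4 cholesterol and 2 elongation genes rose, 3 synthesis and 2 oxidation genes fell, and STARD4 did not pass (adjusted p = 0.0615). Without shNC replicate 1 or 2, 2 elongation genes rose, and without shNC replicate 1, 2 oxidation genes fell and DECR1 did not pass (adjusted p = 0.0664).

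Most genes of DNA replication fell. Of 28 G1/S genes 17 fell, 18 adjusted over the list alone, and the cyclin and kinase genes CCND3 (0.28) and CDK6 (0.24) rose. TYMS, the thymidylate synthase gene, fell from 1144 ± 38.1 to 744 ± 3.20 CPM, MCM7, a replicative helicase gene, by 0.47, PCNA by 0.46 and RRM1 by 0.44 on the log2 scale. Camera placed the list lower (median -0.33, adjusted p = 3.05e-10, adjusted p = 0.244 with an estimated correlation). Of 28 G2/M genes 8 fell, 10 adjusted over the list alone, among them DLGAP5 (-0.72), AURKB (-0.41) and BIRC5 (-0.26), and the phosphatase gene CDC25B rose (0.35), or 3 genes by total counts alone. That set did not pass (adjusted p = 0.0583). Of 25 p53 targets and cell cycle inhibitors 7 rose and 2 fell, 8 and 3 adjusted over the list alone (set adjusted p = 0.0583). The death receptor gene TNFRSF10B (0.51), the cyclin-dependent kinase inhibitor gene CDKN2D (0.49) and PHLDA3 (0.56) rose, and ZMAT3 fell (-0.40). Among 28 apoptosis regulators 6 rose and 4 fell, the same numbers adjusted over the list alone, with CYCS, the cytochrome c gene, higher (0.43) and PMAIP1, which encodes NOXA, lower (-0.66). That set did not pass either (adjusted p = 0.221). Against a 1.2-fold change, 7 G1/S genes passed as lower. With shELOVL5 replicate 1 or 2 left out, 5 and 4 G2/M genes fell, 4 and 3 p53 genes rose, and 2 apoptosis genes rose and 2 fell in both cases. Without shNC replicate 2, 4 p53 and 2 apoptosis genes rose, without shNC replicate 1, 2 apoptosis genes fell, and without any 1 library 1 p53 gene fell.

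Leukemia transcription factor genes and T cell genes mostly fell among those that passed. In the NOTCH1 and T-ALL oncogene list, 9 of 25 genes fell and 4 rose, 10 and 6 adjusted over the list alone (set adjusted p = 0.05003, not past the threshold). LEF1 fell from 874 ± 27.0 to 451 ± 7.64 CPM, TAL1 from 302 ± 8.04 to 189 ± 10.3, MYC from 177 ± 8.36 to 105 ± 4.54 and MYB from 702 ± 8.74 to 536 ± 16.7 CPM. The 4 that rose were RUNX3 (0.80), HES4 (0.84), DTX1 (0.53) and ETV6 (0.47). Of 30 MYC targets and ribosome biogenesis genes 8 fell, also adjusted over the list alone, and 3 others rose when libraries were scaled by total counts only. SRM, the spermidine synthase gene, fell by 0.81, PA2G4 by 0.31 and NOP56 by 0.26 on the log2 scale, and the set was lower by camera (adjusted p = 0.0286, adjusted p = 0.41 with an estimated correlation). Ribosomal protein genes fell in 22 of 32 cases, 25 adjusted over the list alone, including RPS4X (-0.64), RPL3 (-0.59), RPS6 (-0.51) and RPL10 (-0.41). Camera placed them lower (median -0.26, adjusted p = 1.84e-15, adjusted p = 0.41 with an estimated correlation), and 8 passed against a 1.2-fold change. Of 31 T cell receptor and surface genes 11 fell and 4 rose, 14 and 4 adjusted over the list alone (set adjusted p = 0.0583). CD38 fell from 41.7 ± 2.99 to 19.3 ± 0.763 CPM and CD1A by 0.85 on the log2 scale, while CD3E rose from 402 ± 2.84 to 502 ± 19.8 CPM. Without shELOVL5 replicate 1, 5 T cell genes fell and 2 rose, 2 rose without shNC replicate 1 or 2, without shNC replicate 1, 2 MYC list genes rose, and without shELOVL5 replicate 2, 4 fell.

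Mitochondrially encoded genes rose in 11 of 15 cases and fell in 2, 13 and 2 adjusted over the list alone. MT-CO1 rose from 5659 ± 144 to 7741 ± 284 CPM and MT-ND4 from 2803 ± 35.1 to 4085 ± 188 CPM. Both ribosomal RNA genes fell, MT-RNR2 from 4418 ± 198 to 3019 ± 115 CPM and MT-RNR1 with a log2 fold change of -1.12. MT-CO2 had a log2 fold change of 0.27 that did not pass (adjusted p = 0.0607). It did pass by DESeq2 (adjusted p = 0.0383), limma-voom (0.0165), robust=FALSE (0.0187), total counts alone (0.037) and with a replicate block (0.0213). Without shELOVL5 replicate 1 its log2 fold change was 0.16, and without replicate 2 it was 0.36. The list was higher by camera (median 0.37, adjusted p = 2.12e-09, adjusted p = 0.41 with an estimated correlation). Mitochondrial transcripts made up 2.62% of counts in both shNC libraries and 3.30% and 3.11% in shELOVL5. Nuclear-encoded oxidative phosphorylation genes rose in 5 and fell in 5 of 30 cases, 7 and 5 adjusted over the list alone (set adjusted p = 0.499). COX4I1 fell from 233 ± 2.65 to 111 ± 0.316 CPM and ATP5F1B by 0.20 on the log2 scale, while UQCRFS1 (0.41) and COX6C (0.48) rose. Glycolysis and hypoxia genes rose in 9 and fell in 9 of 30 cases, the same numbers adjusted over the list alone (set adjusted p = 0.757). TPI1 fell from 321 ± 0.437 to 203 ± 0.136 CPM, PFKP by 0.37 and PKM by 0.28 on the log2 scale, and PGAM1 rose from 493 ± 1.02 to 662 ± 5.37 CPM. Of 9 replication-dependent histone genes H2AC6 (1.46), H2BC21 (1.32) and H2BC12 (1.10) rose at levels under 7 CPM, the same 3 adjusted over the list alone (set adjusted p = 0.0583). With all 4 libraries, H2BC12 did not pass by DESeq2 (adjusted p = 0.116), with a replicate block (0.0501) or with no low-count filter (0.0843). Nor did it pass by limma-voom (adjusted p = 0.056). With shELOVL5 replicate 1 or 2 left out, 1 histone gene rose, and 2 and 3 oxidative phosphorylation genes rose. Without shNC replicate 1 or 2, 8 and 2 of these rose, and without shELOVL5 replicate 2, 1 fell and ATP5F1B did not pass (adjusted p = 0.0587). H2BC21 did not pass without shNC replicate 1 (adjusted p = 0.053) or either shELOVL5 library (0.0741 to 0.089), nor H2BC12 without shNC replicate 2 (0.165) or either shELOVL5 library (0.136 to 0.169).

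Signalling and adhesion genes changed in part. Migration and adhesion genes rose in 11 and fell in 6 of 27 cases, also adjusted over the list alone (set adjusted p = 0.0645). The integrin genes ITGA5 (73.8 ± 2.43 to 136 ± 5.47 CPM) and ITGB1 (177 ± 5.05 to 261 ± 1.98 CPM) rose, and ITGA4 (-0.51) and RHOH (-0.48) fell. The fibroblast-associated genes THY1 and FN1 rose with them. Immediate early genes rose in 6 of 28 cases, with the dual-specificity phosphatase gene DUSP6 lower (-1.32), also adjusted over the list alone (set adjusted p = 0.0691). JUND rose from 168 ± 6.93 to 295 ± 7.12 CPM, JUN by 0.40 and DUSP2 by 0.82 on the log2 scale. JAK-STAT genes rose in 8 and fell in 4 of 28 cases, 9 and 4 adjusted over the list alone (set adjusted p = 0.221), with JAK1 (0.45) and IL2RG (0.26) higher and STAT5A lower (-1.08). Interferon response genes rose in 5 of 27 cases, also adjusted over the list alone (set adjusted p = 0.0824), including IRF1 (0.58), STAT2 (0.52) and ISG15 (0.38). With every library kept, ISG15 did not pass by limma-voom (adjusted p = 0.0564), robust=FALSE (0.0523) or no low-count filter (0.0981). PI3K pathway genes rose in 5 and fell in 4 of 29 cases, also adjusted over the list alone (set adjusted p = 0.454), with PIK3R2 (0.49) and PIK3R1 (0.32) higher and EIF4EBP1 (-0.76) and PIK3CG (-0.50) lower. NF-kB targets rose in 2 and fell in 3 of 17 cases, also adjusted over the list alone (set adjusted p = 0.527), with TRAF1 (1.33) and RELB (0.47) higher and NFKBIB (-0.33), CD83 (-0.39) and REL (-0.32) lower. Without shELOVL5 replicate 1, 5 migration genes rose and 3 fell, 4 JAK-STAT genes rose and 2 fell, 2 PI3K genes rose, and NFKBIB (adjusted p = 0.0733), CD83 (0.138) and REL did not pass. Without shELOVL5 replicate 2, 6 migration and 4 JAK-STAT genes rose, 2 JAK-STAT and 2 PI3K genes fell, and STAT2 and ISG15 did not pass (adjusted p = 0.072 and 0.246). Without shNC replicate 1, 6 migration and 3 interferon genes rose and ISG15 did not pass (adjusted p = 0.086), nor did ISG15 (0.0757) or CD83 (0.0502) without shNC replicate 2. Immediate early genes fell in 2 cases without shNC replicate 1 or shELOVL5 replicate 2.

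**Figure D3:**
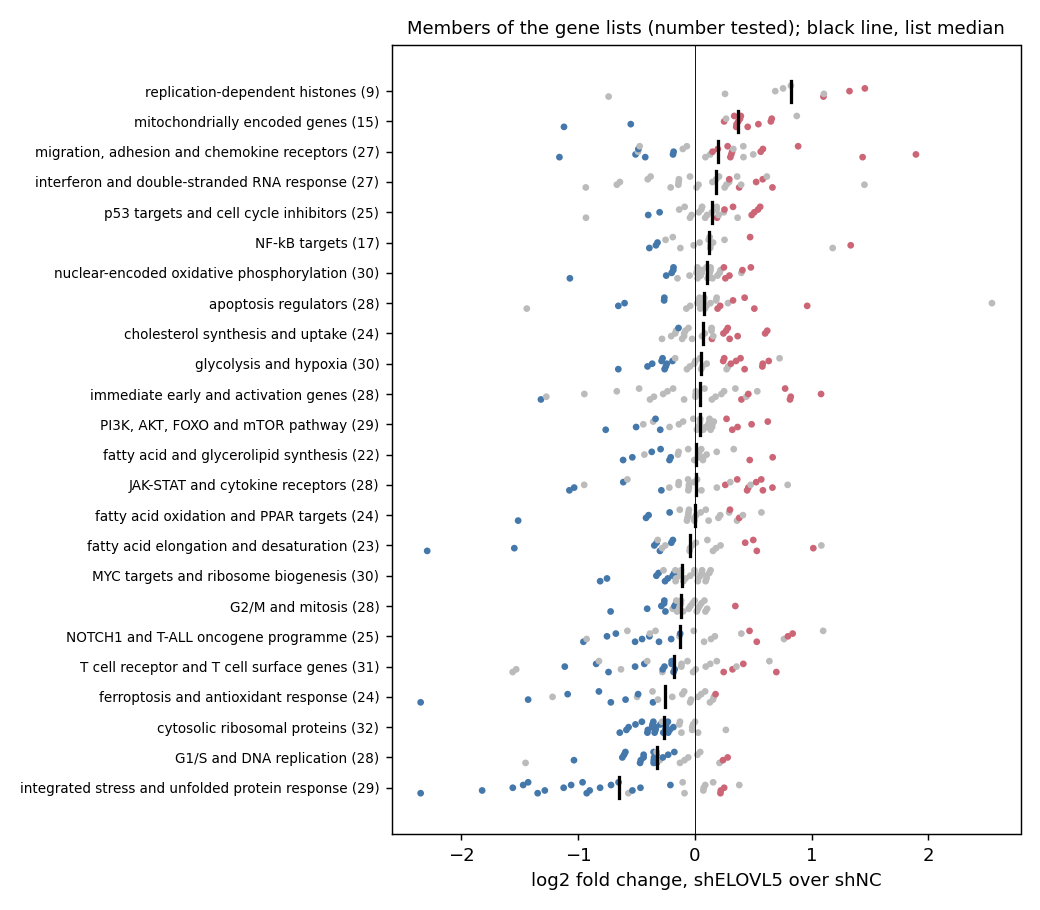
Log2 fold change of shELOVL5 over shNC (horizontal axis) for the tested members of 24 gene lists, 1 point per gene, with the number tested in brackets and a black line at the median. Red points passed as higher, blue as lower and grey did not pass, and the integrated stress list has a median of -0.65.

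Few markers of other cell types had enough counts to be tested. Of 14 B cell markers 5 were tested, and CD79A fell from 40.4 ± 4.46 to 25.7 ± 1.27 CPM, also adjusted over the list alone (set adjusted p = 0.221), and BLK, CD79B and EBF1 did not pass. Of 15 myeloid markers 4 were tested. The markers CST3, AIF1, CD68 and CD14 did not pass in edgeR (adjusted p = 0.116 to 0.896, set adjusted p = 0.662), nor over the list alone, and only CST3 had an unadjusted p under 0.05 (0.0331). By DESeq2 and limma-voom the count was also 0. AIF1 had 114 and 115 counts in shNC but 8 and 162 in shELOVL5, and passed as lower without shELOVL5 replicate 2 (log2 fold change -3.90, adjusted p = 0.00102). Of 12 erythroid markers 2 were tested (set adjusted p = 0.38). KLF1 fell at about 1 CPM (-2.18, adjusted p = 0.0499), also adjusted over the list alone, while EPOR did not pass. KLF1 did not pass without any 1 of the 4 libraries (log2 fold change -2.22 to -2.14). Nor did it pass by limma-voom (adjusted p = 0.0612), with a replicate block (0.0801), robust=FALSE (0.0538), total counts alone (0.053) or no low-count filter (0.0806). Of 15 epithelial and fibroblast markers 6 were tested, and THY1 (62.4 ± 0.658 to 82.8 ± 3.90 CPM) and FN1 (0.885 ± 0.335 to 2.46 ± 0.568 CPM) rose, the same 2 adjusted over the list alone (set adjusted p = 0.14), and SPARC, COL1A1 and KRT8 did not pass. Without shNC replicate 1, or without either shELOVL5 library, 1 of the 2 passed.

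A sequence singled out after the results were seen, TCCAAAC or CCAAACA, was sought in annotated 3′ UTRs. Shares cover only the 9965 scanned genes with a mean of at least 8 CPM, without ELOVL5. Either form was present in 28.1% of the lower genes among them (468 of 1668), 10.4% of the higher (133 of 1274) and 13.8% of the others (966 of 7023). Named genes were looked up whether scanned or not, and ELOVL5 and KLF1 were not among the 9965. Among the named genes that fell, CYB5R4, SCD, DLGAP5, ZMAT3, CD38 and PIK3CG carried both as TCCAAACA. ELOVL5, CCR2, KCNQ3, LEF1, TPI1, RPL10 and KLF1 carried TCCAAAC, and SLC7A11, ALDH1A2, MARCKS, HADHA, TAL1, SRM and COX4I1 carried CCAAACA. The 3′ UTRs of ASS1, TRIB3, ATF4, PSAT1, PHGDH, SLC7A5, HACD3, TYMS and MYC held neither. Nor did those of many other named genes that fell, such as EGFL7, SREBF1, FTL, PCNA and RPL3. PIK3R2, a named gene that rose, carried TCCAAAC.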

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

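All alternatives were planned except the elongation list without ELOVL5, chosen after seeing the data, where camera lost the call (adjusted p = 0.455) and fry kept it (adjusted p = 0.0372). No gene called both by the reported fit and by an alternative changed sign. ELOVL5 kept its direction and side of the threshold under all 14 alternatives (log2 fold change -2.32 to -2.26). Of the named-gene results under the alternatives, 1715 kept direction and side of the threshold, 74 lost the call, 9 gained it and 2 reversed. The 2 reversals, AIF1 at 0.49 and EPOR at 6e-04, came without shELOVL5 replicate 1 and were not past the threshold with or without it, and without shELOVL5 replicate 2 the values were -3.90 and -0.39. With no low-count filter 899 genes were higher, 105 of them at least 2-fold, with 31428 genes tested. DESeq2 gave 105 genes at least 2-fold higher, and the cause was not tested. Against a 1.2-fold change, a stricter hypothesis by construction, 408 genes were higher, 641 lower and 111 higher by at least 2-fold. Leaving out 1 library leaves a group with 1 sample, assumed to vary like the other group, and gave 696 to 1347 higher, 1176 to 1616 lower and 105 to 263 genes at least 2-fold higher, with the lowest counts without either shELOVL5 library. Scaling by total counts only gave 1933 higher and 1674 lower, with a median shift over all genes of 0.042. Same-numbered replicates did not deviate together (correlation -0.0148 across 17461 genes), and a replicate block gave 1551 higher and 1902 lower genes. The 7 list calls made by camera at the preset correlation were all lost with an estimated one, where the lowest adjusted p was 0.12. That setting rests on the 2 residual degrees of freedom of the design, so it has little power. The estimated correlation was below the preset 0.01 for the stress (-0.0079), G1/S (-0.0269) and elongation (-0.0371) lists. Correlation therefore did not cause the loss of these calls. It was above 0.01 for the MYC, ferroptosis, ribosomal protein and mitochondrial lists (0.0369 to 0.6). Under fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 6 of the 7 passed and mitochondrially encoded genes did not (adjusted p = 0.0516). A further 8 lists that camera did not call passed under fry (adjusted p = 0.0221 to 0.0448), lower for glycerolipid synthesis, oxidation, G2/M and T cell genes and higher for cholesterol, interferon, migration and epithelial or fibroblast genes. List counts moved by over 1.5 times in 146 of the alternative results and by less in 638. At this depth and n = 2, the smallest simulated changes were mostly missed (16% recovered), so a gene that did not pass is not shown to be unchanged.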

Other observations

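The tests in this part were chosen after the results were seen. Beyond the lists fixed in advance, many genes of protein synthesis fell. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 12 fell, 15 adjusted over the list alone, led by AARS1 (-0.78), YARS1 (-0.69) and CARS1 (-0.68). Of 22 amino acid transporter genes 8 fell and 2 rose, 10 and 3 adjusted over the list alone. They included SLC6A9 (-1.20), SLC1A5 (-0.96) and, higher, SLC1A1 (2.06), whose mean was under the 5 CPM of the naming rule. Both lists were lower by camera (adjusted p = 3.33e-14 each, adjusted p = 0.0516 with an estimated correlation). Of 41 translation factor genes 14 fell and 4 rose, 16 and 6 adjusted over the list alone. That set was lower by camera (median log2 fold change -0.058, adjusted p = 1.56e-07, adjusted p = 0.128 with an estimated correlation). Since these lists were chosen after the results were seen, their p-values are not independent support. EEF2 fell from 2642 ± 73.9 to 1393 ± 7.42 CPM and EEF1A1 from 7360 ± 58.7 to 5174 ± 54.5 CPM.

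Several abundant transcripts outside the lists changed strongly. SERBP1, which encodes an mRNA-binding protein, fell from 499 ± 0.807 to 102 ± 5.96 CPM (log2 fold change -2.29, adjusted p = 1.79e-09). CFL1, the cofilin gene, fell from 948 ± 32.5 to 351 ± 3.54 CPM and the developmental transcription factor gene SOX4 from 1120 ± 16.4 to 550 ± 23.2 CPM. The long noncoding RNAs NEAT1 (75.8 ± 0.507 to 190 ± 9.32 CPM) and NORAD (262 ± 2.08 to 458 ± 4.24 CPM) rose, as did MYH9, a nonmuscle myosin gene (0.60).

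Transcripts with the hexamer CCAAAC in the 3′ UTR were shifted downward, and of 4096 hexamers it had the most negative score (z = -14.34, against at most 4.58 in 100 shuffles). Also past the shuffles were the overlapping CAAACA (-8.83) and TCCAAA (-6.93) and, upward, TTGCAC (4.86). Median log2 fold changes were -0.227 for 333 genes with TCCAAACA, -0.113 for 572 with TCCAAAC, -0.086 for 662 with CCAAACA, -0.008 for 1098 with the hexamer only and 0.009 for 7300 without it. A trend with UTR length, base composition or expression would have been removed by regression, yet the octamer genes stayed at -0.251 relative to genes without the hexamer. UTRs with 2 or more sites had a median -0.067 relative to those with 1 (permutation p = 7.6e-03), which longer UTRs or octamers do not account for, since the difference after regression, averaged over comparisons within each kind of site, was -0.101 (permutation p = 2.0e-04). Seed pairing of the ELOVL5 hairpin, by which SERBP1, EIF4H, CYB5R4 and SRPK1 could have fallen independently of ELOVL5, stays open: the sequence was chosen from these same fold changes, the hairpin sequence was not used, and TCCAAAC, present 3 times in the ELOVL5 transcript, is in 19.6% of transcripts.

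The fall of the stress response list was then set against such sites in its own members. Of 15 members without the hexamer anywhere in the transcript 7 fell (46.7%). The share was 11.6% among 4920 other genes without it (exact two-sided binomial test, p = 8.0e-04). These 15 lack such sites by selection, so the count shows only that members of the list fell without sites of their own. Of 8 with the hexamer only, ATF4 among them, 5 fell, against 15.4% of such genes (exact two-sided binomial test, p = 3.2e-03). That pooled count cannot exclude a site acting in ATF4 itself, since its targets on the list could then fall without sites of their own. The hexamer of ATF4 was not in its 3′ UTR, however. Genes with the hexamer only outside the 3′ UTR had a median log2 fold change of -0.013, and 14.8% were lower. For genes without it anywhere these were 0.027 and 11.6%. As a class such genes were thus little shifted, whereas ATF4 fell by 1.29 on the log2 scale. For the 6 members with a heptamer or the octamer such sites stay open, as all 6 fell, more often than the 24.6% of other genes with such sites (p = 2.2e-04) but also more often than the 7 of 15 (Fisher exact p = 0.0456). Besides ATF3 and DDIT4, those of the 15 that did not fall were CRELD2, DNAJB9, PDIA4, SDF2L1, SEL1L and XBP1. These are unfolded protein response genes, whereas of the 6 only CALR is, so the difference may reflect the make-up of the list. After regression on transcript length, base composition and expression the list median was -0.553, outside the range of 10000 random lists (-0.201 to 0.245). Those lists held genes drawn independently, so their range does not allow for members that move together. The binomial and Fisher tests above also count members as independent, so their p-values do not allow for it either. The list was also singled out for its fall. Loss of ELOVL5, silencing of an unintended regulator by the hairpin, and different culture states such as amino acid supply could each lower ATF4 and its targets, and with a single hairpin and 1 control none was tested.

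The rise of ACTA2 and ACTG2 was weighed in the same way. Reads of ACTB or ACTG1 assigned to ACTA2 would need these to rise as much, but the log2 rise of ACTA2 exceeded the larger of theirs by 3.083. Reads of ACTA2 as the source of all ACTG2 counts would need an equal ratio of ACTG2 to ACTA2 in both groups, but it was 1.767 in shNC and 0.662 in shELOVL5, while for the gain of ACTG2, 54.29% of that of ACTA2, this stays open, as counts per gene cannot separate the 2. Admixed fibroblasts or smooth muscle cells would bring all their abundant transcripts, but COL1A2, COL3A1, DCN and LUM had 0 counts in every library. That allows 1.01% of the gain of ACTA2. Yet 9 stromal transcripts, these 4 included, together gained 6.41% of it, or 45.9% with THY1, FN1 and SPARC. THY1 was already at 62.4 CPM and SPARC at 28.5 CPM in shNC, where the 4 had 0 counts. Of the 9, MYH11 had a lower mean in shELOVL5 (1.79 against 2.11 CPM), and DES, COL1A1, COL6A1 and COL6A2 had higher means. Higher activity of the actin-responsive factors SRF and MRTF may be involved: of 27 other targets 11 rose and 3 fell, 12 and 3 adjusted over the list alone, and the set was higher by camera (adjusted p = 0.0001174, adjusted p = 0.1 with an estimated correlation), though whether this follows ELOVL5 loss or the fall of CFL1, which encodes an actin-severing protein, was not tested.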
